A study of Homo sapiens with 56 samples.

How the data were processed

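Total RNA from 4 CTCL cell lines was labelled with biotin and hybridized to Affymetrix arrays, 1 array for each of 56 samples. After 96 hours the untreated wells were counted and all wells were diluted by the factor that brought the untreated cells back to their starting density, and fresh medium was added 48 hours later. Samples were grouped by line, day and treatment from the labels, which gave 14 groups of 4 arrays. The control of each comparison was the untreated group of the same line and day. The arrays used were all of untreated or cobomarsen wells, so effects of any oligonucleotide cannot be told apart from those of inhibiting miR-155.

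The deposited values are signal intensity from MAS5 on a linear scale, per the submitters' processing notes. The mean after trimming 2% of values from each end was 499.9 in each array, so all arrays had been scaled to a common level. The median signal ranged from 56.4 to 91.7 and the upper quartile from 380 to 466. Between arrays of 1 group the correlation of log2 values was 0.971 to 0.989. The 4 arrays per group and the signal over background limit the precision, and genes near background were not tested.

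The table held 54675 probe sets, of which 62 were controls, 41091 had 1 gene symbol, 1801 several and 11721 none. Probe sets with several symbols or none were left out of the gene tests and counted apart. For each of 19775 genes the probe set with the highest mean over the 56 arrays was used. Values were analysed as log2(value + 16). A gene was tested in a comparison when its mean over the arrays compared reached the median of all values (log2 6.49, signal 74.0).

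Group means were fitted with limma 3.58.1 in R 4.3.3 as 1 model over the 56 arrays (42 residual degrees of freedom), with variances moderated along an intensity trend (median prior degrees of freedom 8.47). Comparisons were cobomarsen against untreated in each line and day, the difference of that effect between days, day 8 against day 4 in untreated wells, the difference of the day 8 effect between the 4 lines (moderated F-test) and its average. Tests were two-sided with Benjamini-Hochberg adjustment over the genes tested in each comparison, at 0.05. A total of 20 gene lists was tested with camera at a preset correlation of 0.01, adjusted over lists in each comparison. Camera with an estimated correlation and fry were alternatives. The probe set for the miR-155 host transcript was tested by exact permutation. Overlaps were set against the number that independent lists would share, with the days of a line taken as 1 list, since they are not independent. Where a group mean of a named gene lay under a signal of 74.0, signals are given in place of a fold or log2 change, which would depend on the value added before the logarithm. Medians of lists and counts of called genes include such genes. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 was used for mapping and drawing.

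The gene lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. The rule took, in each comparison of treatment, up to 8 called genes with the largest rise and 8 with the largest fall whose groups did not overlap, and up to 4 called members of each list with the largest change. It also allowed all members of the miR-155 list and the host transcript, the 10 largest rises and falls called in all 4 lines, the 5 largest in each direction for the day differences, untreated wells and average, and the 10 smallest p-values of the F-test. Not every gene the rule allowed is named. The choice among them was made after their values were seen, and genes whose call was lost under an alternative were mostly passed over. The counts of stability in the closing section cover 438 pairs of gene and comparison, those passed over included, so that they are not raised by this choice.

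Alternatives were log2(value + 1) and log2(value + 64), no filter, a filter at the 75th percentile, quantile normalization, every probe set on its own, only the arrays of the lines compared, variances moderated without the trend, and leaving out each array in turn. Alternatives chosen after seeing the data were HuT78 with cobomarsen array 1 alone, and the F-test and the average without HuT78. Counts of called genes were also computed for all 35 divisions of 8 arrays into 4 and 4, or for 100 random draws where there are more. The steps were tested on simulated data of the size of MJ at day 8. Of seeded changes that were tested, 59.4% of those of log2 0.5 and 81.1% of those of log2 1 were recovered, with 0 of the wrong sign and 4 unchanged genes called. A list of 40 unchanged genes had a camera p of 0.0890 and a list raised by 0.3 one of 4.29e-24. The simulated genes were drawn independently of each other, with 1 SD per gene in all groups. These list values therefore do not test the preset correlation. A test of genes with miR-155 seed sites needs 3′ UTR sequences and was not run.

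The numbers in the sample titles form 1 series for HuT102 and MJ and another for MyLa and HuT78. This possible batch cannot be told apart from line, but each treatment comparison lies within 1 line.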

Results

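Messenger RNA was measured on 56 Affymetrix arrays from 4 human cell lines of cutaneous T-cell lymphoma (CTCL), HuT102, MJ, MyLa and HuT78. Cells were grown with cobomarsen, an oligonucleotide inhibitor of the microRNA miR-155, or left untreated. HuT102, MJ and MyLa were harvested at day 4 and day 8, which the series names as the times for direct and downstream targets, and HuT78 at day 8. Each of the 14 groups of line, day and treatment held 4 arrays, so the number of arrays limits the precision. The labels do not say that the 4 arrays came from separate cultures, so p-values measure the spread between these samples. In limma that spread was pooled for each gene over the 14 groups of all 4 lines. It can therefore differ from the spread within the groups compared, and so can the standard errors. HuT102 and MJ carry the virus HTLV-1. The values are the authors' MAS5 signal. Between 10940 and 11985 genes were tested in each comparison, and a gene was called at a limma adjusted p under 0.05. After a log2 change the ± sign gives its standard error, and after a signal the standard deviation (SD, n = 4).

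The question common to all comparisons was which genes change when miR-155 is inhibited. A list of 47 published miR-155 targets, of which 41 had a usable probe set, rose in HuT102, MJ and MyLa at both days. PICALM, which helps assemble clathrin coats, went from 1284 ± 259 to 5946 ± 670 in HuT102 at day 4, and its log2 change was 1.54 to 2.21 over the 6 comparisons of these lines. The unconventional myosin MYO10 rose by 1.49 to 3.09, the scaffold protein SDCBP by 0.79 to 1.65, the RNA-binding protein CARHSP1 by 1.17 to 1.90 and the transcriptional repressor BACH1 by 0.81 to 1.65. JARID2, a partner of Polycomb repressive complex 2, rose by 0.72 to 1.11. INPP5D, the lipid phosphatase SHIP1, rose by 0.31 to 1.52, and the transcription factor FOXO3 by 0.29 to 1.64. In all, 17 members were called higher in each of the 6 comparisons.

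Of the listed targets, 25 of 38 measured rose and 2 fell in HuT102 at day 4 (median log2 change 0.66), and 23 of 38 rose and 2 fell at day 8 (0.68). In MJ 26 of 37 rose and 1 fell at day 4 (0.64), and 27 of 38 rose and 3 fell at day 8 (0.70). In MyLa 28 of 38 rose and 2 fell at day 4 (0.56), and 27 of 38 rose and 2 fell at day 8 (0.61). Adjusted over the list alone, the numbers that rose were 26, 24, 28, 30, 28 and 29 in the same order. The list stood apart from other genes in each of the 6 (camera, adjusted p from 7.76e-21 to 4.54e-10). Members that fell included MSH6, a mismatch repair gene, by 0.87 ± 0.08 in HuT102 at day 8, and TP53INP1 and CTLA4 in MyLa at day 8, with log2 changes of -1.21 ± 0.12 and -1.49 ± 0.31. In HuT78 the same list did not rise, and 3 of its 31 measured members were called higher and 4 lower (median log2 change -0.13, adjusted p = 0.643). PICALM stood at 3376 ± 408 with cobomarsen and 3702 ± 275 without in HuT78 (log2 change -0.14 ± 0.11, limma adjusted p = 0.383). The mean change of the list differed between the 4 lines at day 8 (limma moderated F-test, adjusted p = 1.14e-20).

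**Figure D1:**
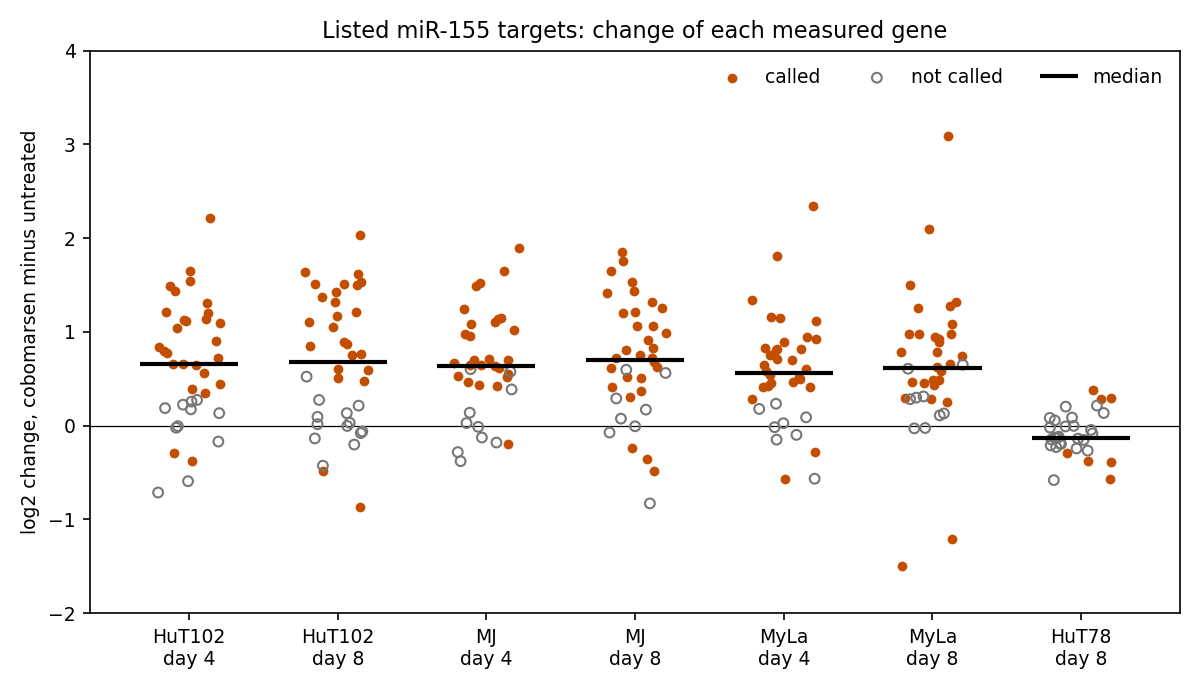
Each point is the log2 change (cobomarsen minus untreated) of 1 measured member of the miR-155 target list in 1 of the 7 comparisons; filled points passed the test and bars mark the median. The medians lie between 0.56 and 0.70 in HuT102, MJ and MyLa and at -0.13 in HuT78.

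The transcript that gives rise to miR-155 was read by 1 probe set, which the array's annotation assigns to both MIR155 and MIR155HG. Its signal was near background in HuT78, at 36.2 ± 20.1 with cobomarsen and 29.9 ± 7.72 without, and between 11499 and 29906 on average in the groups of the other lines. With cobomarsen it was higher in HuT102, at 25232 ± 1163 against 19475 ± 1188 at day 4 and at 29906 ± 1850 against 24428 ± 1096 at day 8. It was lower in MJ, at 11499 ± 1156 against 14658 ± 487 at day 4 and at 15311 ± 629 against 19956 ± 496 at day 8, and in MyLa at day 8, at 21002 ± 1064 against 24943 ± 1277. In these 5 comparisons no array of 1 group lay inside the range of the other, and the exact permutation p was 0.0286, the smallest that 4 arrays against 4 allow (0.0400 after adjustment over 7 comparisons). In MyLa at day 4 the signals were 22332 ± 567 and 23909 ± 1570 (exact permutation p = 0.143), and in HuT78 the exact permutation p was 0.600. All of these tests were two-sided.

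In HuT102 at day 4, cobomarsen raised the collagen gene COL1A1 6.90-fold, from 151 ± 13.4 to 1143 ± 192 (log2 change 2.79 ± 0.20, limma adjusted p = 1.31e-16). The B cell attractant CXCL13 rose by 2.47 ± 0.19 and the transcription factor BHLHE22 by 2.61 ± 0.29. The cytokine gene IL24 fell from 301 ± 37.5 to 29.8 ± 18.2 and lymphotoxin beta, LTB, fell from 1151 ± 147 to 280 ± 47.3. PTGS2, which encodes cyclooxygenase 2, fell by 1.57 ± 0.10 and COL6A3 by 1.87 ± 0.35. Genes of the list of FOXO targets and quiescence rose together, 12 of 17 and none lower (14 adjusted over the list alone, adjusted p = 3.42e-11), among them TXNIP (1.27 ± 0.13), SESN3 (1.36 ± 0.21) and PIK3IP1 (1.04 ± 0.15). That list shares FOXO3 and S1PR1 with the miR-155 list. Among the other lists, PI3K pathway components share INPP5D and RICTOR with it, and Th2 and regulatory genes share MAF and CTLA4. The p53 targets share TP53INP1, and the JAK-STAT, MAPK-ERK, T cell and integrated stress lists share 1 gene each. Of 30 cell cycle genes 19 fell and none rose (22 lower and 1 higher adjusted over the list alone, adjusted p = 1.88e-08), such as FOXM1 (-0.87 ± 0.18) and MKI67 (-0.55 ± 0.11). Of 21 genes of cholesterol and fatty acid synthesis 12 fell and 2 rose (15 and 2 adjusted over the list alone, adjusted p = 3.45e-05), with DHCR7 at -1.25 ± 0.11 and the desaturase SCD at -0.96 ± 0.11. The interferon response list was called lower (9 of 28 lower, 1 higher, adjusted p = 0.0176) and the NF-kB list higher (9 of 22 higher, 3 lower, adjusted p = 0.0191), each with adjusted p = 0.217 with an estimated correlation. Cytosolic ribosomal proteins (none of 22 called singly) and oxidative phosphorylation (6 of 31 higher, 1 lower) were also called higher as lists, with adjusted p = 0.00190 and 0.0402, and 0.526 and 0.654 with an estimated correlation. In all, 2671 of 11600 genes were called, 1163 higher and 1508 lower, and 190 of them changed at least 2-fold.

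At day 8 the HuT102 gene BHLHE22 had risen from 36.6 ± 21.2 to 1452 ± 222, the growth factor receptor FGFR3 from 11.6 ± 1.57 to 771 ± 181 and the amino acid transporter SLC7A2 from 57.1 ± 47.8 to 1368 ± 209. The untreated signals of these 3 genes lay near background, so no fold is given. The urokinase gene PLAU went from 217 ± 31.6 to 4013 ± 920 (log2 change 4.10 ± 0.15, limma adjusted p = 3.85e-28), and the costimulatory receptor ICOS rose by 2.90 ± 0.10. Lower were IL24 (323 ± 32.1 to 22.6 ± 19.2), COL6A3 (5143 ± 287 to 586 ± 127), the B cell survival factor TNFSF13B (3001 ± 477 to 332 ± 44.2) and granzyme B, GZMB (-2.49 ± 0.27). The interferon response list fell as a group, 27 of 29 genes lower and 1 higher (the same counts adjusted over the list alone), with a median log2 change of -1.41 and an adjusted p of 7.12e-19. USP18 (-2.37 ± 0.21), MX2 (-2.01 ± 0.13) and OAS1 (-1.98 ± 0.20) were among them. Of the 30 cell cycle genes 27 fell and 1 rose (the same adjusted over the list alone, median -0.66, adjusted p = 1.92e-14), with CDK1 at -1.11 ± 0.11 and CCNA2 at -1.05 ± 0.08.

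The FOXO list in HuT102 at day 8 had 15 of 17 genes higher and 1 lower (the same adjusted over the list alone, median 0.79, adjusted p = 7.62e-10), including TXNIP (2.02 ± 0.13) and the pro-apoptotic gene BCL2L11 (1.89 ± 0.16). Cholesterol and fatty acid genes fell in 17 of 21 cases and rose in 1 (the same adjusted over the list alone, median -0.72, adjusted p = 7.72e-11), including SCD (-2.35 ± 0.11), DHCR7 (-2.13 ± 0.11) and the desaturase FADS2 (-1.54 ± 0.14). Several further lists were called with the preset correlation and not with an estimated one. These were NF-kB targets (14 higher and 3 lower of 22, with CCL22 at 1.94 ± 0.28; adjusted p = 0.000866, and 0.0913 with an estimated correlation), Th2 and regulatory genes (8 higher and 2 lower of 19; 0.0132 and 0.0913), p53 targets (9 higher and 3 lower of 18; 0.0266 and 0.0774), PI3K pathway components (9 higher and 2 lower of 20; 0.0233 and 0.184) and hypoxia and glycolysis (2 higher and 11 lower of 24; 0.00147 and 0.344). Oxidative phosphorylation genes were called higher in 22 of 31 cases and lower in 1 (0.000742 and 0.5), and ribosomal protein genes in 4 of 22 cases (0.0188 and 0.610). In all, 4682 of 11671 genes were called, 2212 higher and 2470 lower, 794 of them at least 2-fold. The upper quartile of the array signal was also higher with cobomarsen, by 25.9 on average, with no overlap of the groups.

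In MJ at day 4 the receptor gene KLRB1, which encodes CD161, rose from 67.3 ± 47.3, near background, to 828 ± 60.0 (limma adjusted p = 7.37e-11). ENPP2, which encodes autotaxin, rose by 2.97 ± 0.09 and ANTXR2 by 3.06 ± 0.24. Interferon gamma, IFNG, fell from 1662 ± 129 to 231 ± 57.5 and the OX40 ligand TNFSF4 from 8442 ± 465 to 1284 ± 79.8. IL4 fell from 261 ± 77.7 to 34.8 ± 20.7, and the interleukin genes IL6, IL5 and IL13 were also lower, with log2 changes of -2.39 ± 0.22, -1.58 ± 0.16 and -1.24 ± 0.15. Of 18 p53 targets 9 fell and 2 rose (10 and 2 adjusted over the list alone, adjusted p = 0.00142), with CDKN1A at -0.74 ± 0.08 and TIGAR at -0.71 ± 0.05. Of 15 T cell receptor and identity genes 5 rose and 1 fell (the same adjusted over the list alone, adjusted p = 0.0204), with LEF1 at 1.42 ± 0.21 and CD3D at 0.47 ± 0.09. The lists of NF-kB targets (2 higher and 11 lower of 23), interferon response (2 higher and 13 lower of 26) and integrated stress and unfolded protein response (11 of 22 lower, none higher) were called lower, with adjusted p from 3.77e-05 to 0.000251. With an estimated correlation their adjusted p were 0.0578, 0.0578 and 0.0584. CCL22 (-2.12 ± 0.28), IFIT3 (-1.74 ± 0.12) and ASNS (-0.78 ± 0.09) were members of these. In all, 3265 of 11985 genes were called, 1561 higher and 1704 lower, 360 of them at least 2-fold. The upper quartile of the array signal was higher with cobomarsen by 19.5 on average, with no overlap.

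At day 8 KLRB1 stood higher in MJ, at 1855 ± 201 against 43.5 ± 24.7, and ENPP2 14.1-fold higher, at 3601 ± 119 against 245 ± 53.8. TSC22D1 rose by 3.95 ± 0.10 on the probe set used, while its other probe set tested was called lower, at -0.65. IFNG was 19.9-fold lower, at 163 ± 42.6 against 3496 ± 385, and IL26 went from 679 ± 62.2 to 55.0 ± 18.9. The kinase gene NEK6 fell from 765 ± 67.5 to 43.0 ± 33.5, and TNFSF4 had a log2 change of -3.16 ± 0.08. Of the 30 cell cycle genes 20 fell and none rose (22 adjusted over the list alone, median -0.33, adjusted p = 4.08e-07), with CDC20 at -0.74 ± 0.07 and BUB1B at -0.72 ± 0.06. The p53 targets were lower in 11 of 18 cases and higher in 1 (12 and 1 adjusted over the list alone, median -0.49, adjusted p = 8.39e-05), with GDF15 going from 254 ± 24.8 to 52.0 ± 22.8 and AEN at -0.86 ± 0.11. T cell genes were higher in 6 of 15 cases and lower in 2 (the same adjusted over the list alone, adjusted p = 0.0164), with LEF1 at 2.16 ± 0.21 and CD247, the zeta chain of the receptor complex, at 0.59 ± 0.07. Interferon response (13 of 26 lower, 1 higher; adjusted p = 8.39e-05, and 0.0566 with an estimated correlation), NF-kB targets (12 of 23 lower, 3 higher; 0.0147 and 0.225), MAPK-ERK feedback (9 of 20 lower, 3 higher; 0.0346 and 0.246), integrated stress (10 of 22 lower, none higher; 0.00881 and 0.246) and cholesterol synthesis (7 of 21 higher, 2 lower; 0.0211 and 0.116) were called with the preset correlation only. DUSP5, a phosphatase that acts on ERK, fell by 1.68 ± 0.12, and the synthase HMGCS1 rose by 1.16 ± 0.09. In all, 4015 of 11939 genes were called, 1800 higher and 2215 lower, 574 of them at least 2-fold. The upper quartile of the array signal (by 18.7 on average) and the GAPDH 3′ to 5′ ratio (by 0.0190) were higher with cobomarsen, with no overlap. At day 4 the MAPK-ERK list had also been called lower (8 of 19 lower, 2 higher; adjusted p = 0.0294, and 0.306 with an estimated correlation).

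In MyLa at day 4 the oxidoreductase gene FMO5 rose 4.88-fold, from 232 ± 24.3 to 1190.0 ± 47.6 (log2 change 2.29 ± 0.30, limma adjusted p = 3.28e-08). MYO10 rose by 2.34 ± 0.19, KLHL5 by 2.12 ± 0.14 and the adhesion molecule CEACAM1 by 2.01 ± 0.40. ZBED2 fell from 387 ± 42.3 to 57.3 ± 13.4, and the transcription factor IKZF2 from 220.1 ± 20.4 to 43.2 ± 18.3. The lipid transporter ABCA12 fell by 2.38 ± 0.30. Of 20 genes of cholesterol and fatty acid synthesis 15 fell and none rose (the same adjusted over the list alone, median -0.35, adjusted p = 1.26e-07), with DHCR7 at -0.92 ± 0.11 and STARD4 at -0.74 ± 0.09. Of 17 p53 targets 10 fell and 2 rose (11 and 3 adjusted over the list alone, median -0.39, adjusted p = 0.000298), with TP53I3 at -0.98 ± 0.10 and ZMAT3 at -0.70 ± 0.09. In all, 2938 of 11183 genes were called, 1496 higher and 1442 lower, 222 of them at least 2-fold.

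At day 8 KLHDC7B rose in MyLa from 55.3 ± 15.3, near background, to 801 ± 83.2, and MYO10 from 91.5 ± 19.0 to 892 ± 110.0. ZBED2 fell to 20.3 ± 19.1 from 396 ± 33.9. Also lower were CFAP95 (1039 ± 140.1 to 67.2 ± 12.4), HLA-DQB2 (-3.48 ± 0.38) and CYP1A1, a cytochrome P450 that responds to the aryl hydrocarbon receptor (-3.23 ± 0.27). HILPDA, a lipid droplet gene induced by hypoxia, went from 7885 ± 1813 to 1172 ± 78.8, and the glycolytic regulator PFKFB4 fell by 2.89 ± 0.23. Cholesterol and fatty acid genes fell in 18 of 20 cases with none higher (18 lower and 1 higher adjusted over the list alone, median -0.61, adjusted p = 7.33e-12), including MSMO1 (-1.28 ± 0.08) and SCD (-1.26 ± 0.11). The p53 targets fell in 10 of 17 cases with none higher (the same adjusted over the list alone, median -0.47, adjusted p = 2.41e-07), with RRM2B at -1.71 ± 0.13 and ZMAT3 at -1.44 ± 0.09. The cell cycle list moved up, with 18 of 30 genes higher and none lower (19 adjusted over the list alone, median 0.35, adjusted p = 1.27e-05), such as the cyclin CCNE2 (1.71 ± 0.12) and the replication helicase gene MCM7 (0.88 ± 0.09). Hypoxia and glycolysis genes (12 of 24 lower, 2 higher; adjusted p = 0.00174, and 0.481 with an estimated correlation), oxidative phosphorylation (17 of 31 lower, none higher; 0.000221 and 0.517) and PI3K components (8 of 17 higher, 1 lower; 0.0170 and 0.253) were called with the preset correlation only. In all, 4563 of 10940 genes were called, 2566 higher and 1997 lower, 473 of them at least 2-fold.

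**Figure D2:**
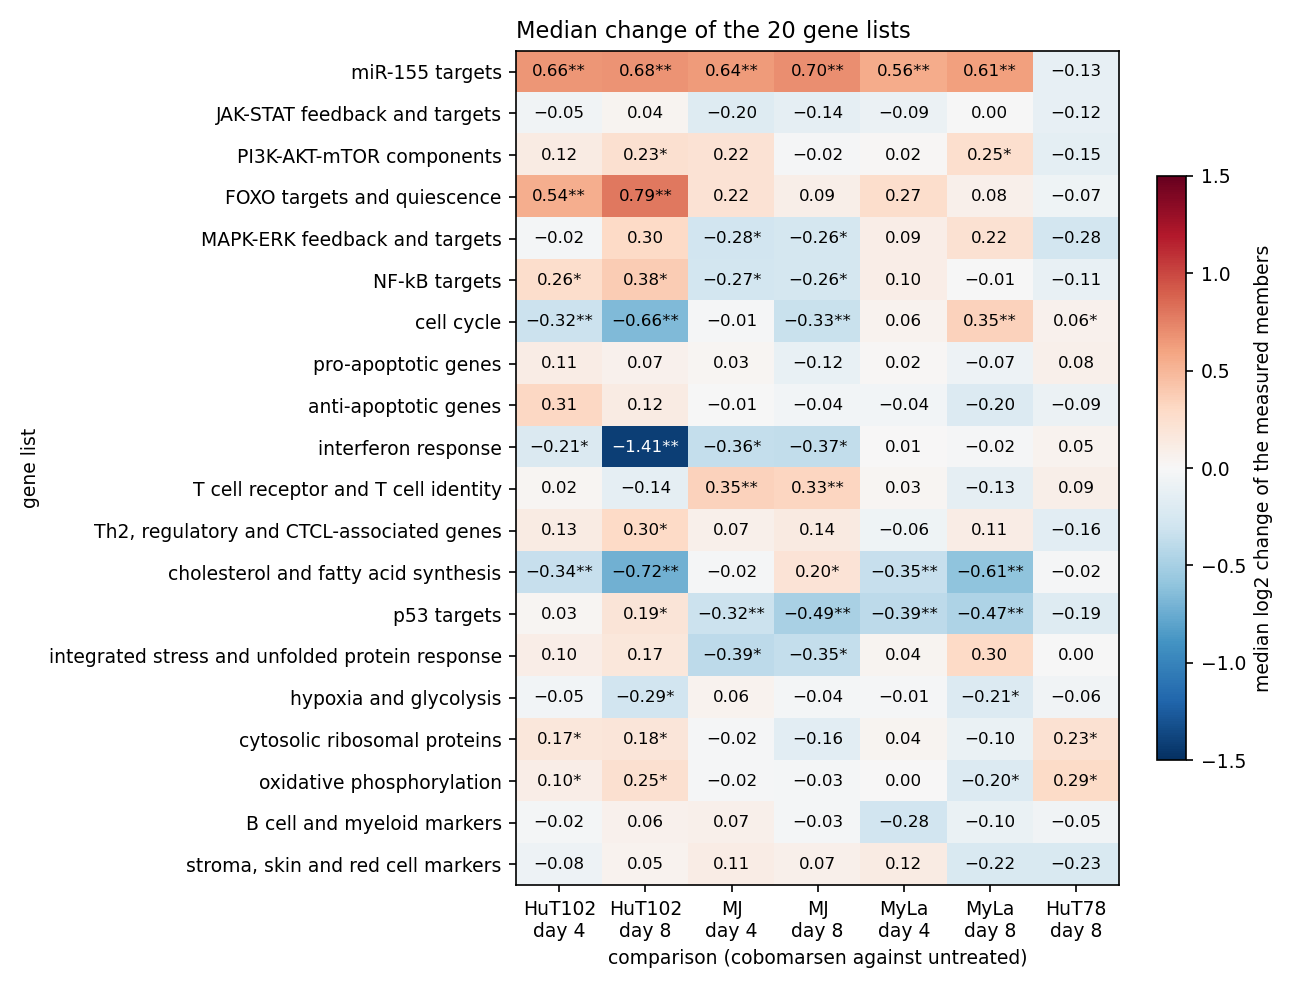
Each cell gives the median log2 change (cobomarsen minus untreated) of the measured members of 1 of 20 gene lists in 1 of 7 comparisons. Cells with 1 star passed the list test with the preset correlation, and cells with 2 stars also with an estimated correlation, which was so for 23 of the 49 called cells.

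**Figure D3:**
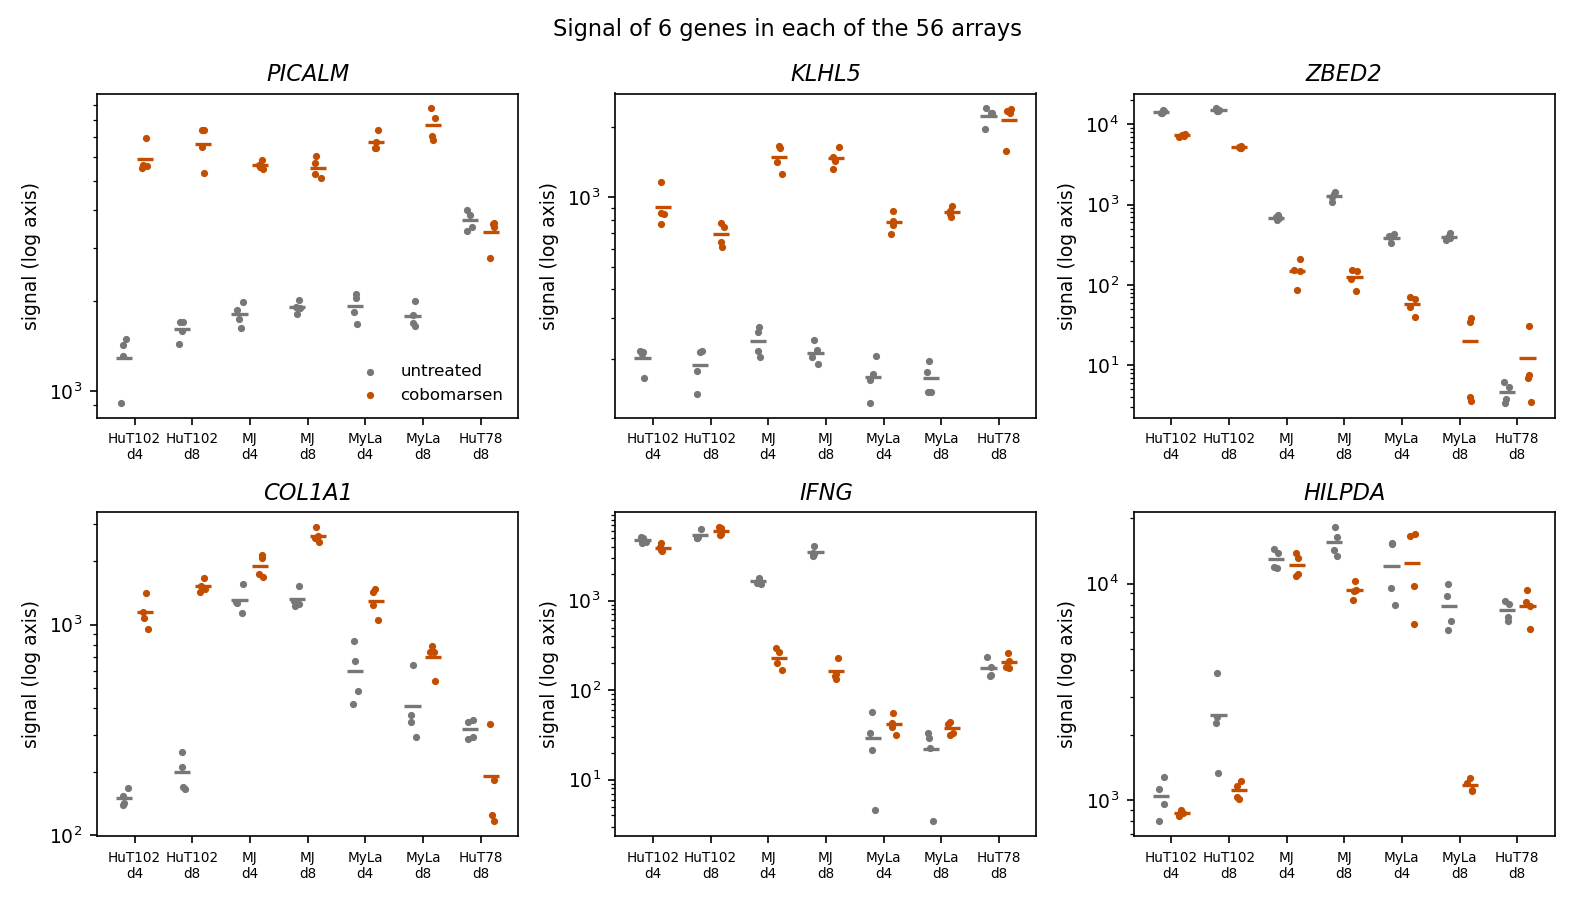
Signal of 6 genes on a logarithmic axis in each of the 56 arrays, with short lines at the group means; grey points are untreated and orange points cobomarsen arrays. PICALM and KLHL5 stood higher and ZBED2 lower with cobomarsen in HuT102, MJ and MyLa at both days, while in HuT78 PICALM and KLHL5 had log2 changes of -0.14 and -0.08 and were not called, and ZBED2 lay under the signal needed for a test.

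In HuT78 at day 8 the changes were small. The metallothionein gene MT1X rose from 3682 ± 85.3 to 5910 ± 386 (log2 change 0.68 ± 0.10, limma adjusted p = 1.37e-05), and it was the only gene still called when the model was fitted to the 8 HuT78 arrays alone (adjusted p = 0.0176). In the model of all 56 arrays 2414 of 10950 genes were called, 1169 higher and 1245 lower, and 35 of them changed at least 2-fold. Smooth muscle actin, ACTA2, was called at 2425 ± 309 against 1480 ± 135 (log2 change 0.70 ± 0.08), and the kinetochore gene SKA3 at 791 ± 203 against 410 ± 25.1 (0.88 ± 0.17). Oxidative phosphorylation genes (23 of 31 higher, none lower, 26 adjusted over the list alone; adjusted p = 6.66e-15), cytosolic ribosomal proteins (8 of 22 higher, none lower, 16 adjusted over the list alone; 5.22e-07) and cell cycle genes (8 of 30 higher, 3 lower; 0.0492) were called higher. With an estimated correlation the adjusted p of these lists were 0.480, 0.512 and 0.480. The cobomarsen arrays were uneven: the upper quartile of the signal was 380 to 385 in arrays 2, 3 and 4, against 431 in array 1 and 422 to 443 in the untreated arrays. Between pairs of cobomarsen arrays the SD of the log2 difference was 0.425 to 0.540, against 0.326 to 0.387 between untreated arrays. The model of all 56 arrays pools the variance over groups and does not use the wider spread of this group alone. Chance was not excluded for the count of 2414, since 2 of the 35 divisions of the 8 arrays gave as many, the real one included, and the other gave 3294. Groups did not overlap for 9.12% of the HuT78 genes, where chance gives 2.86%, against 25.4% to 42% in the 6 other comparisons.

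The difference between the day 8 and the day 4 effect was tested in the lines with both days. It was called for 835 of 11604 genes in HuT102 (376 with a higher log2 change at day 8, 459 with a lower one), for 161 of 11929 in MJ (45 and 116) and for 1878 of 11028 in MyLa (1059 and 819). A lower log2 change can be a stronger fall. In HuT102 the difference was called for FGFR3 and SLC7A2, whose mean cobomarsen signals were 129 and 529.7 at day 4 and 771 and 1368 at day 8. SLC7A2 was also called lower at day 8 than at day 4 in untreated HuT102 (limma adjusted p = 0.000253). Part of its difference therefore came from the untreated wells. For FGFR3 the rise of the cobomarsen signal was also smaller in log2 than the difference of the effects. Part of that difference thus came from untreated wells, which lay near background (11.6 ± 1.57 at day 8). The log2 change of glutamine synthetase, GLUL, went from 0.58 to -2.07 (difference -2.64 ± 0.33). In untreated HuT102 GLUL rose by 2.51 ± 0.24 between the days, so most of this difference came from the untreated wells. In MJ the difference was called for NEK6 and for the transcriptional repressor GFI1, whose cobomarsen signals went from 91.5 ± 7.76 and 98.8 ± 11.9 at day 4 to 43.0 ± 33.5 and 19.8 ± 8.22 at day 8, near background. For NEK6 this fall was smaller in log2 than the difference of the effects, so part of the latter came from untreated wells. In MyLa HILPDA, at 0.00 at day 4, reached -2.71 (-2.71 ± 0.30), PFKFB4 went from -0.59 to -2.89 (-2.30 ± 0.32) and ZNF324 from -1.24 to 1.15 (2.39 ± 0.43). Among list averages, the effect on the interferon list in HuT102 moved by -1.08 (adjusted p = 1.93e-15). The effect on the cell cycle list moved by -0.31 in HuT102, -0.33 in MJ and 0.31 in MyLa (adjusted p = 1.79e-07, 8.60e-08 and 5.96e-07). The average of the miR-155 list did not pass this test in HuT102, MJ or MyLa (changes of 0.06, 0.06 and 0.05, adjusted p = 0.331, 0.469 and 0.384). Across genes, which are not independent replicates, the effects at the days correlated at r = 0.74 in HuT102, 0.82 in MJ and 0.56 in MyLa. The MJ count ranged from 66 to 139 when 1 array was left out, and was 431 with the MJ arrays alone and 99 without the intensity trend.

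Untreated wells also changed between day 4 and day 8, by 1002 called genes in HuT102 (528 higher at day 8), 191 in MJ (136 higher) and 1446 in MyLa (729 higher). In HuT102 interferon-induced genes were among those that rose, with IFITM1 at 2.43 ± 0.09 and IFI27 at 2.67 ± 0.39, and the early response gene FOS fell by 2.38 ± 0.45. In MJ MZB1 fell by 0.73 ± 0.10 and SH3BP5 by 0.74 ± 0.09. In MyLa the neuropeptide gene PMCH rose by 1.59 ± 0.23 and the water channel AQP4 by 1.85 ± 0.30. The interferon response list rose by a median log2 change of 1.32 in untreated HuT102 (adjusted p = 3.48e-73) and by 0.29 in the cobomarsen wells of that line (adjusted p = 0.000514, and 0.0970 with an estimated correlation). The cell cycle list fell in both arms of HuT102 (medians -0.17 untreated and -0.52 cobomarsen, adjusted p = 8.18e-07 and 3.26e-24) and in cobomarsen MJ (-0.28, adjusted p = 1.23e-17). It was called lower in untreated MyLa (-0.19, adjusted p = 1.01e-05, and 0.106 with an estimated correlation) and not called in untreated MJ (0.06, adjusted p = 0.0685) or cobomarsen MyLa (0.07, adjusted p = 0.239). The cholesterol and fatty acid list rose in untreated HuT102 (0.20, camera adjusted p = 4.26e-05, and 0.00644 with an estimated correlation). In cobomarsen HuT102 it fell (-0.28, camera adjusted p = 0.000125, and 0.00762 with an estimated correlation). Part of its larger difference at day 8 in HuT102 therefore lay in the untreated wells. Leaving out 1 array gave counts of 619 to 1140 in HuT102, 97 to 201 in MJ and 815 to 1678 in MyLa, and MJ gave 483 with its own arrays alone. The days are separate harvests, so time and harvest cannot be told apart.

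**Figure D4:**
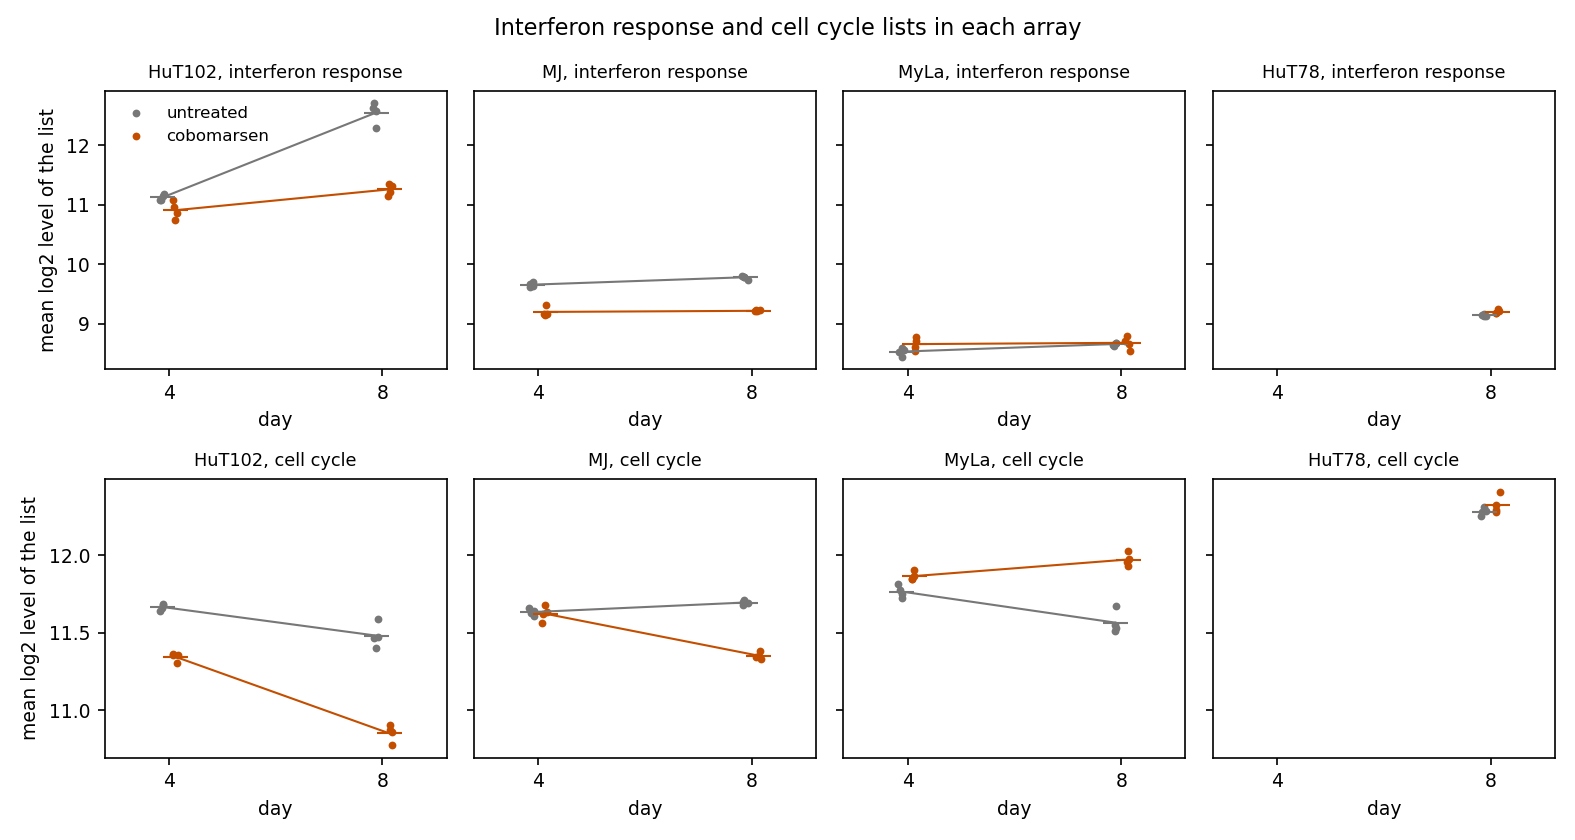
Mean log2 level of the interferon response list (top) and the cell cycle list (bottom) in each array, by day, with lines joining the group means; grey is untreated and orange cobomarsen. In HuT102 the untreated arrays gained on the interferon list between the days, and in MyLa the cell cycle list lies higher with cobomarsen at day 8.

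Whether the day 8 response differed between the 4 lines was tested for each gene, and 7526 of 11634 genes were called (limma moderated F-test). The count includes differences between HuT78, where the miR-155 list did not rise, and the other lines. Among the 10 smallest p-values were TNFSF4 (adjusted p = 2.75e-38), ENPP2 (1.29e-33) and ICOS (7.26e-26). TNFSF4 changed by 1.95 in HuT102, -3.16 in MJ and -1.25 in MyLa, and ICOS by 2.90 in HuT102 and -0.68 in MyLa. List averages differed between lines for 19 of the 20 lists, with adjusted p = 9.46e-25 for both the cell cycle and the cholesterol list. The exception was the JAK-STAT list (adjusted p = 0.0573). The possible array series (HuT102 with MJ, MyLa with HuT78) is part of the difference between lines and cannot be told apart from it.

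Part of the response was nevertheless shared. In HuT102, MJ and MyLa at both days, 230 of 9766 genes were called higher in all 6 comparisons, and 94 were called lower. With the genes called at both days in each line as 1 list per line, independent lists would share 8.69 and 10.7. At day 8 alone 394 of 9969 genes were called higher in the 3 lines and 285 lower (74.3 and 85.7 for independent lists). After the values were seen, KLHL5, the transcription factor MYB and IL6 were chosen as examples beside PICALM, MYO10 and ZBED2. KLHL5 rose by 1.81 to 2.70, MYB by 0.97 to 2.05, and ZBED2 and IL6 fell in each. The log2 changes of IL6 ran from -2.39 to -0.58 and those of ZBED2 from -3.21 to -0.97 in HuT102 and MJ, while in MyLa ZBED2 lay near background with cobomarsen. The call of IL6 in MyLa at day 4 was lost with log2(value + 1), without the filter and with quantile normalization, and that of ZBED2 in HuT102 at day 4 with log2(value + 1). MYB in MyLa at day 8 rose by 1.65 on the probe set used, while its other probe set tested was called lower, at -0.93. Between pairs of these lines at day 8 the effects correlated weakly across genes, at r = 0.28 for HuT102 and MJ, 0.11 for HuT102 and MyLa and 0.24 for MJ and MyLa. Of the genes called in both lines of these pairs, 480 of 2188, 1037 of 2322 and 694 of 2058 changed in opposite directions. With HuT78 the correlations were -0.08, -0.11 and -0.10 for HuT102, MJ and MyLa. There 613 of 1093, 692 of 955 and 711 of 1118 genes called in both lines changed in opposite directions. Over all 4 lines at day 8, 30 of 9402 genes were called higher in each and 18 lower. This is fewer than the 47.7 and 35.8 that HuT78 would share by chance with the genes called in the other 3 lines. HuT78 shared 118 higher and 145 lower genes with MJ (181 and 244 for independent lists), 238 and 169 with MyLa (295 and 223) and 245 and 235 with HuT102 (226 and 281). CARHSP1, the glutamate decarboxylase gene GAD1 and the proton pump subunit ATP6V1C1 were among the first, and PTGS2, TNF and CISH, a feedback inhibitor of cytokine signalling, among the second. None of these 6 was called in HuT78 with the HuT78 arrays alone. The average effect over the 4 lines was called for 4508 of 11634 genes, 2098 higher and 2410 lower, with KLHL5 at 1.68 ± 0.07 and PICALM at 1.38 ± 0.05. HuT78, where the log2 changes of KLHL5 and PICALM were -0.08 and -0.14, counts in this average.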

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

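The tests of array distance and of the miR-155 list in HuT78 were chosen only after the result was seen.

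HuT78 gave 2414 called genes at day 8 although its miR-155 list did not rise. The median log2 change of that list, -0.13, is part of the pattern itself and so tests no explanation of it. Apart from the list, the miR-155 host transcript lay near background in HuT78, at 36.2 with cobomarsen and 29.9 without. Its group means were 11499 to 29906 in the other lines. This argues against relief of repression by miR-155 as the source of the calls, although miR-155 itself was not measured. Under quantile normalization 1667 genes were called, which argues against the signal distribution as the whole cause. Cobomarsen array 1 lay as close to the untreated arrays as they lay to each other (distance ratio 0.968), while arrays 2, 3 and 4 had ratios of 1.90, 1.85 and 2.13, so a difference between arrays or wells rather than treatment may account for the calls. Chance was not excluded, since the highest other division, with cobomarsen array 1 among the untreated and untreated array 4 among the treated, called 3294 genes, which points to a structure of the samples.

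The cell cycle list fell in HuT102 and MJ and rose in MyLa at day 8. With quantile normalization the MyLa median was 0.39, which argues against array scaling. Between day 4 and day 8 the list fell by 0.19 in untreated MyLa (median log2 change -0.19, adjusted p = 1.01e-05, and 0.106 with an estimated correlation) and stood at 0.07 in cobomarsen wells, so the rise against untreated wells may come in part from the untreated wells. Wells of both arms were diluted by 1 factor, set by the untreated cells, and an effect of density was not tested. A biological difference between the lines stays open.

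The interferon response list fell in HuT102 far more at day 8 than at day 4. With quantile normalization its day 8 median was -1.39, which argues against array scaling. In untreated HuT102 the list rose by 1.32 from day 4 to day 8, and by 0.29 with cobomarsen, so the larger difference at day 8 may rest on a rise in untreated wells that cobomarsen wells did not share to the same extent. Whether cobomarsen held back that rise or the untreated wells differed for another reason stays open.

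Chance was taken as excluded where under 5% of the divisions of the arrays, the real one included, called as many genes; for HuT78 the share was 2 of 35. It was excluded for these counts, each given with the highest other count: HuT102 at day 4 2671 (274) and day 8 4682 (1239), MJ at day 4 3265 (314) and day 8 4015 (430), MyLa at day 4 2938 (597) and day 8 4563 (1575). The same held for untreated HuT102 at 1002 (200), MJ at 191 (5) and MyLa at 1446 (101) and for the average at 4508 (1794), with 1 of 35 or 1 of 100 divisions as large. A share of 1 of 35 is the smallest that 35 divisions allow, and shares were not adjusted for the number of counts. The labels do not say that arrays came from separate cultures, so exchanging arrays cannot exclude a difference between cultures or harvests. For the difference between lines, at 7526 (3487), 1 of 100 draws was as large. Those draws exchanged treatment within each line, and so assume no treatment effect in any line. They cannot decide whether a difference between the lines arose by chance. For the difference between days the counts were 835 (1914), 161 (280) and 1878 (2357) in HuT102, MJ and MyLa. Of 100 draws, 3, 2 and 3 were as large. These draws exchanged the days within each arm, and so assume no change between the days in either arm. They include higher counts than the real ones and cannot decide whether a difference of the effects arose by chance. The larger draws kept most arrays of a day together and exchanged the days in 1 or both arms, which points to the difference between the days as a structure of the samples.

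Differences between groups passed their test for 835, 161 and 1878 genes between days in HuT102, MJ and MyLa and for 7526 genes between lines. List averages differed between lines for 19 lists, and between days for 8 lists in HuT102, 1 in MJ and 9 in MyLa.

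Single arrays stood far from the other 3 of their group in 16 of 212 groups tested, where chance gives about 1 in 20. The median signal of MyLa day 8 cobomarsen array 1 was 67.3 (58.3 to 59.7 in the others). The upper quartile was 422 in HuT78 untreated array 4 (441 to 443) and 431 in HuT78 cobomarsen array 1 (380 to 385). The ratio of GAPDH signal at the 3′ end to the 5′ end was 0.898 in MJ day 8 untreated array 4, 0.951 in MJ day 8 cobomarsen array 4, 0.940 in HuT78 untreated array 2 and 0.850 in MyLa day 4 cobomarsen array 1. The share of signal in the top 100 probe sets was 9.80% in MJ day 4 cobomarsen array 3 and 9.22% in MyLa day 8 cobomarsen array 2. List levels apart were 9.97 for the miR-155 list in MyLa day 8 untreated array 1, 11.31 for the cell cycle list in HuT102 day 4 cobomarsen array 3 and 9.33 for the interferon list in MJ day 4 cobomarsen array 4. Gene levels apart were FMO5 at 1261 in MyLa day 4 cobomarsen array 1, KLHDC7B at 78.1 in MyLa day 8 untreated array 2, and PICALM at 6946 in HuT102 day 4 cobomarsen array 1 and 2768 in HuT78 cobomarsen array 3.

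Probe sets without a single gene symbol, which the gene tests did not use (1 of them, for the miR-155 host transcript, was tested apart), were called in number: 458 in HuT102 at day 4, 1229 at day 8, 579 in MJ at day 4, 714 at day 8, 548 in MyLa at day 4, 1036 at day 8 and 486 in HuT78.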

How the results depend on the processing

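Among the alternatives of HuT78, array 1 alone was chosen only after the result was seen. The miR-155 list was tested again with log2(value + 64), quantile normalization, camera with an estimated correlation, fry and each array left out. It was called higher in HuT102, MJ and MyLa at both days under each of these, with medians from 0.51 to 0.73 when 1 array was left out. The list was not tested under the other alternatives. Of 438 pairs of named gene and comparison, 374 kept direction and call under each alternative fixed in advance and each array left out. Calls were lost for 23 of 433 with log2(value + 1), 1 with log2(value + 64), 8 without the filter, 0 of 311 at the 75th percentile, 9 of 437 with quantile normalization, 3 with every probe set, 37 with only the arrays of the lines compared, 4 without the trend, and in 103 of 4008 cases of 1 array left out. KLHL5 in HuT78, not called, ranged from -0.14 (without untreated array 3) to 0.065 (without cobomarsen array 3). For the lists other than miR-155, 26 calls were lost with an estimated correlation. Genes near background were not tested, and 4 arrays per group limit what small changes can be called. The tests of miR-155 seed sites were not run.

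With every probe set on its own, and so more tests, counts were 4272 and 8002 in HuT102, 5357 and 6525 in MJ and 5042 and 7797 in MyLa at day 4 and day 8, 3068 for the day difference in MyLa, 1566 in untreated HuT102, 12726 between lines and 7693 for the average. With only the arrays of the lines compared, counts were 431 for the day difference in MJ, 483 in untreated MJ and 1 in HuT78, and without the trend 99 for the day difference in MJ; the cause was not tested. With fry the HuT78 miR-155 list was called lower at -0.13 (adjusted p = 0.0449; 0.643 and 0.714 with camera), and the cause was not tested. HuT78 array 1 alone against the untreated arrays, with fewer arrays, gave 9 genes.

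Leaving out 1 array moved the count in HuT78 from 1306 (without cobomarsen 4) to 3616 (without cobomarsen 1), with 1582 without untreated 1. In untreated HuT102 it ranged from 619 (without day 8 untreated 4) to 1140, in untreated MJ from 97 to 201 (day 4 untreated 1 and 2 gave 118 and 97, day 8 untreated 1 gave 120) and in untreated MyLa from 815 to 1678 (day 8 untreated 3 and 4 gave 815 and 948). The day difference in MJ ranged from 66 to 139, with 75 and 106 without day 4 untreated 1 and 2, 66 and 105 without day 4 cobomarsen 3 and 4, 96, 91 and 81 without day 8 untreated 1, 2 and 3, a fall of over 1.5 times without untreated 4 as well, and 90 without day 8 cobomarsen 3.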

Other observations

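The lists of JAK-STAT feedback, pro-apoptotic, anti-apoptotic, B cell and myeloid, and stroma, skin and red cell genes were called in none of the 7 comparisons, with lowest adjusted p of 0.0831, 0.0670, 0.0629, 0.446 and 0.260. Single members changed all the same. In HuT102 at day 8 the cytokine signalling inhibitor SOCS3 fell by 1.85 and the anti-apoptotic gene BCL2L1 rose by 0.93. In MJ at day 8 the kinase gene PIM1 had a log2 change of -1.76, STAT3 of -1.46 and the cytokine gene OSM of 1.51. PIM1 and STAT3 were called lower in HuT102, MJ and MyLa at both days, with log2 changes of -1.76 to -0.41 and -1.46 to -0.33. In MyLa at day 8 BMF, a pro-apoptotic gene, fell by 1.31.

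Probe sets other than the one used were tested for 194 of 378 called pairs of gene and comparison, and 163 had another called the same way and 2 another called the other way. Of 28 exact tests of array quality, 4 had the smallest p that 4 arrays against 4 allow, 0.0286 (adjusted p = 0.2): the upper quartile of the signal in HuT102 at day 8 and in MJ at day 4 and day 8, and the GAPDH 3′ to 5′ ratio in MJ at day 8. So few tests at this smallest p cannot pass the adjustment, which therefore does not show that quality was alike.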
